A study of Homo sapiens with 18 samples.

How the data were processed

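The series measured transcripts by RNA sequencing in 2 human acute myeloid leukaemia cell lines, OCI-AML2, which carries normal NPM1, and OCI-AML3, which carries a mutated NPM1 that places the protein in the cytoplasm. In each line, CASP2, the gene of the protease caspase-2, had been targeted with CRISPR-Cas9, and 2 clones per line were labelled as knockouts. Together with the parental cells this made 6 groups of 3 libraries, 18 in all. Groups and replicate numbers came from the sample titles. Per the labels' protocols, untreated cells were grown in RPMI medium with serum for less than 2 weeks, RNA was isolated on columns, and libraries were prepared at a BGI Americas facility.

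The deposited table gives TPM (length- and depth-scaled transcript abundance) per gene and library, per the file headers. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. TPM keeps no record of the number of reads, so the depth of each library is unknown and no interval for counting error is given. All 18 value columns matched a sample and 0 were left without one.

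The table turned out not to list each gene once. It holds 6999 lines with 4816 gene symbols, of which 4793 matched 1 Entrez identifier in a RefSeq gene table (assembly GRCh38.p14, used for names and for which genes neighbour each other). These lines hold 5069 distinct sets of 18 values, 1732 of them repeated in 2 or 3 lines, and 1319 sets stand under 2 different symbols. In 97.4% of the lines the log2 ratio was at least 0.95 between the parental lines, in both OCI-AML3 clones or in OCI-AML2 clone 1, so the table holds genes selected for a change and is only part of each library. The values of the distinct sets sum to between 170141 and 199403 TPM per library. Shares of changed genes therefore describe the table, not the transcriptome.

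Each set of values was counted once, and a gene name was given only where the structure of the table settled it. Repeats of a set differed in the replicate order of OCI-AML3 clone 1. Where 2 lines with different symbols held the same set, 1374 of 1375 such pairs lay in a single increasing order of identifiers, and in the 194 sets seen in 2 lines of the first replicate order and 1 of the other, the 2 lines of the first order always carried the same symbol. A symbol was accepted for 575 sets repeated under it, for 1076 sets through the replicate order, for 673 sets in a single line without a difference between the parental lines, and for 222 sets through the order of the stacked lists. In total 2546 sets (50.2%) had a settled symbol, and 2108 lines carried a symbol that a settled one contradicted. The log2 ratio of 0.6 behind the single-line rule was lowered after 2 conflicts had been seen, so the absence of conflicts under it (0 of 673) is no independent check. The list-order rule gave the same values as the other rules for 459 symbols and other values for 1. Which genes neighbour each other entered none of these rules, but the list-order rule used the sizes of the clone changes. Correlations of these changes between neighbouring genes are therefore no fully independent check of the rules, and they were not uniform. Over sets whose printed and settled symbols differed, the correlation of neighbours in OCI-AML2 clone 1 was 0.272 with the settled symbols (548 genes) and -0.0235 with the printed ones (549 genes). In OCI-AML2 clone 2 it was 0.149 against 0.114 (permutation p = 0.006 for the printed symbols). In the OCI-AML3 clones it was -0.0106 and -0.0114 with the settled symbols and 0.00957 and 0.0129 with the printed ones. Sets without a settled symbol entered all fits and counts but are not named.

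Expression was compared as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 18 libraries and an intensity trend in the empirical Bayes step. Tested were the 4413 sets with at least 1 TPM in at least 3 libraries, 2296 of them with a settled symbol, and 656 were below that minimum. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values, while folds quoted as ratios are ratios of mean TPM. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. A gene was counted as changed in a cell line only if both clones passed in the same direction, and as changed differently between lines only if all 4 pairwise differences of clone changes passed in the same direction. For genes changed in a line the log2 values quoted are the mean of both clones, and the adjusted p-values are those of the single clones. For the difference between lines, the log2 values, SE and adjusted p-values quoted are those of the difference between the mean clone changes. The call itself rests on the 4 pairwise differences. CASP2 was compared between single groups also by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

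Before the data were examined, the design, the alternatives, the rule for named genes and 28 gene lists were fixed. The rule named CASP2, NPM1, PIDD1 and CRADD; per line the 12 genes with the largest rise and the 12 with the largest fall among genes changed in both clones, with at least 5 TPM in the higher group and no overlap of libraries; the 8 largest in each direction for the difference between lines and for both lines; the 10 largest in each direction between parental lines; and up to 4 changed and 2 other members of each list. NPM1, PIDD1 and CRADD are not analysed here, and 1 gene that the rule selected between parental lines is not used here. Genes that only a neighbour scan named were chosen after their values were seen. Members of near-identical families (HLA-DRB1, IFITM1, IFITM3, MT1A, MT2A, NCF1, ORM1, AKR1C3 and the RHOXF2 pair) are uncertain, since reads may have been split between copies.

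The 28 lists hold 759 entries, of which 183 had a settled symbol, and members below are those tested among them. Of the lists, 26 had a tested member and 13 had at least 5 and were tested with camera from limma, with a preset inter-gene correlation of 0.01 and again with an estimated one. These p-values were adjusted over the 13 lists. Members all had a settled symbol, whereas the set test compared them with all other tested sets, with or without one. Sets with a symbol changed more often (in both OCI-AML3 clones 1876 of 2296, against 2959 of all 4413), which the test did not allow for. For the clones the test used the mean change of both, so a list can pass through 1 clone. The ribosome biogenesis and mitochondrially encoded lists had 0 members with a settled symbol and have no result. Counts of list members adjusted over the list alone were the same as those over all genes tested in all 26 lists for each of 4 comparisons, except for 1 list in OCI-AML2.

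Correlations of comparisons that share parental libraries were set beside simulated unchanged clones against those libraries, and overlaps only beside the number that independent lists give. The fits were tested on simulated data before use. For the comparison of both OCI-AML3 clones over 4413 genes, the procedure recovered 82.1% of changes of 0.5 on the log2 scale and 100% of changes of 1 and of 2, and called 2 of 4213 unchanged genes. Changes were planted only in genes above 2 on the log2(TPM + 1) scale in OCI-AML3 parental cells, equally in both clones. Recovery at lower levels and variation between clones were not simulated. The simulation left 4213 of 4413 genes unchanged, whereas 2959 of 4413 sets were called in the data. The adjustment was therefore stricter in the simulation, and neither rate carries over to the data. The alternatives were other pseudocounts (0.1 and 5), no filter or a minimum of 5 TPM, rescaling by medians of ratios over 3389 genes, no intensity trend, only the groups compared, a minimum log2 change of 1, the replicate number as a block, the mean of the clones in place of both, and each library left out in turn. The replicate order of OCI-AML3 clone 1 is not known for 1312 sets, which bears on each result that uses its single libraries: leaving them out, the block, correlations of libraries, principal components and splits that mix the clones. Group means do not depend on it. The scan of neighbouring genes (windows of 15 genes, at least 5 TPM in parental cells, 1000 shuffled gene orders) and its alternatives were chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.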

Results

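Transcripts were measured by RNA sequencing in OCI-AML2 and OCI-AML3 cells, 2 human acute myeloid leukaemia lines that differ in the state of NPM1. Parental cells of each line were compared with 2 clones per line labelled as CASP2 knockouts, with 3 libraries in each of the 6 groups. The comparisons ask what loss of caspase-2 does to gene expression in each line and whether the outcome differs between the lines. Values are TPM as deposited, given as mean ± SD (n = 3 libraries per group unless stated), and the read depth is unknown. The table holds genes selected for a change, so all counts refer to 4413 tested sets of values, 2296 of which could be tied to a gene symbol.

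CASP2, which encodes caspase-2, an initiator protease of stress-induced cell death, was the targeted gene and is given first. In OCI-AML2 its mRNA stood at 35.32, 37.29 and 35.57 TPM in the parental libraries, at 3.93, 3.58 and 3 TPM in clone 1 and at 5.03, 3.27 and 5.06 TPM in clone 2. It fell to 9.72% of the parental level in clone 1 (log2 change -3.05, SE 0.11, adjusted p = 1.7e-13) and to 12.3% in clone 2 (log2 change -2.78, adjusted p = 4.2e-13). In OCI-AML3 it stood at 30.11, 28.12 and 28 TPM in the parental libraries, at 26.34, 27.05 and 27.83 TPM in clone 1 and at 31.09, 35.39 and 29.82 TPM in clone 2. The log2 changes there were -0.08 in clone 1 (adjusted p = 0.537) and 0.15 in clone 2 (adjusted p = 0.240). The difference between the lines was 2.95 on the log2 scale (SE 0.14, adjusted p = 1.5e-12). Exact permutation tests of the log2(TPM + 1) values gave p = 0.1 for clone 1 and clone 2 of OCI-AML2, 0.1 for clone 1 and 0.2 for clone 2 of OCI-AML3, where 0.1 is the smallest p possible. After rescaling by medians of ratios, OCI-AML3 clone 2 passed as higher (log2 change 0.30, adjusted p = 0.0148; the range over 14 alternatives was 0.0148 to 0.590). A frameshift need not lower mRNA, so the mRNA level neither checks nor contradicts the OCI-AML3 labels, and those clones are called clones labelled as knockouts.

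**Figure D1:**
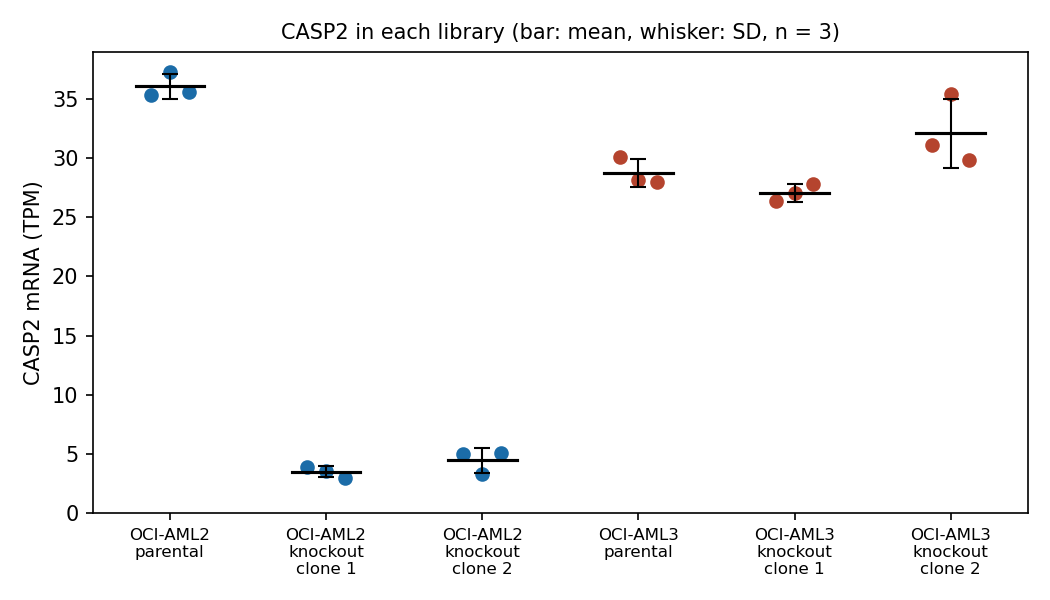
CASP2 mRNA in TPM (vertical axis, from 0) in each of the 6 groups, with 1 point per library and bars for the mean and SD of 3 libraries. The OCI-AML2 clones lie between 3 and 5.06 TPM, below the parental libraries at 35.32 to 37.29 TPM, while the OCI-AML3 groups lie between 26.34 and 35.39 TPM.

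In OCI-AML3, CHI3L1, CYBB and CD14 were among the genes with the largest rises in the clones labelled as knockouts, and CD37 and IFI27 among those with the largest falls. CHI3L1, a secreted glycoprotein of macrophages and neutrophils, rose from 8.29 ± 1.197 TPM to 4745 ± 148 in clone 1 and 5076 ± 150 in clone 2 (573-fold and 613-fold, log2 SE 0.15, adjusted p = 1.2e-18 and 1.1e-18). CYBB, the catalytic subunit of the phagocyte NADPH oxidase, rose from 0.277 ± 0.0569 to 45.5 ± 1.53 and 46.7 ± 0.973 TPM. CD14, the lipopolysaccharide co-receptor of monocytes, rose 51.8-fold and 61.7-fold to 42.1 ± 1.30 and 50.2 ± 2.81 TPM. CD37, a leukocyte tetraspanin, fell from 1105 ± 132 to 33.4 ± 3.03 and 43.7 ± 6.05 TPM. IFI27, an interferon-induced gene, fell from 1525 ± 99.6 to 95.3 ± 6.93 and 29.8 ± 2.97 TPM.

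In the same OCI-AML3 clones PYGM, muscle glycogen phosphorylase, reached 197 ± 3.08 and 222 ± 10.7 TPM from 0.300 ± 0.104. AKR1C3, a steroid-converting aldo-keto reductase, reached 132 ± 7.35 and 130 ± 10.2 TPM from 0.550 ± 0.145. IGFBP3, which binds insulin-like growth factors, reached 314 ± 4.62 and 225 ± 8.95 TPM from 2.85 ± 0.372. NTSR1, the neurotensin receptor, reached 23.9 and 27.2 TPM, and the collagen chain gene COL8A2 25.6 and 23.5 TPM. The small GTPase gene RAB13 reached 26.1 and 23.5 TPM, and DEF6, a guanine nucleotide exchange factor of immune cells, 27.1 and 28.3 TPM. MAGED1 and the zinc finger gene ZNF302 were listed at 0 in the 3 parental libraries and reached 25.4 and 26.9 TPM, and 19.7 and 15.3 TPM. Across these 12 genes the log2 rise was 4.20 to 9.05, and the highest adjusted p was 1.8e-15. Among the falls, the metallothionein gene MT1A went from 89.6 ± 22.8 to 0.727 ± 1.26 and 0.740 ± 0.26 TPM. PLTP, a phospholipid transfer protein, fell from 232 ± 15.9 to 7.22 ± 0.296 and 7.36 ± 0.488 TPM. ST6GAL1, a sialyltransferase, fell from 54.5 ± 2.95 to 1.22 ± 0.127 and 1.62 ± 0.185 TPM. GOT1, the cytosolic aspartate aminotransferase, fell from 24.0 ± 3.14 to 0.0200 ± 0.0346 and 0.0400 ± 0.0346 TPM. S100A16, a calcium-binding protein, fell from 52.4 ± 7.42 to 0.0367 ± 0.0635 TPM in each clone. EEF1A2, a tissue-restricted elongation factor, RUFY4, DTX3, PALM and the receptor kinase LTK completed the 12 largest falls. Their log2 values ran from -5.80 to -4.13 with a highest adjusted p of 3.6e-11. In all, 2959 of 4413 sets changed in both clones, 1267 higher and 1692 lower. Of these 1876 had a symbol. The clone labels rest on no mRNA check in this line, and the selected table overstates the share that changed.

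Of the gene lists in OCI-AML3, 2 of 13 passed the set test with the preset correlation and 0 with an estimated one. Members are the tested genes with a settled symbol, and the other genes of a list have no result. Of all 2296 tested sets with a symbol, 789 were higher and 1087 lower in both OCI-AML3 clones, so most members of any list would be called. Integrated stress and unfolded protein response genes rose, with 6 of 7 members higher and 0 lower (median log2 change 0.99, adjusted p = 0.0181; adjusted p = 0.0834 with an estimated correlation). The list names 25 genes, of which 10 stand in the table and 7 had a settled symbol. Their members included SLC7A11, the cystine transporter (1.80), DDIT3, which encodes the transcription factor CHOP (1.31), and CHAC1, a glutathione-degrading enzyme (1.27). The amino acid transporter gene SLC7A5 was at -0.15 and did not pass. Genes of signals that regulate pluripotency fell, with 14 of 17 members lower and 2 higher (median -0.65, adjusted p = 0.0338; adjusted p = 0.0995 with an estimated correlation). IGF1R, the receptor for insulin-like growth factor 1 (-2.09), SMAD1, a mediator of BMP signalling (-2.06), and FZD3, a Wnt receptor (-1.91), fell, and INHBE, an activin subunit gene (1.54), rose. The second call ended with a minimum of 5 TPM (adjusted p = 0.0678; the range over its alternatives was 0.00556 to 0.0678). Each count here was the same adjusted over the list alone.

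Among the OCI-AML3 lists that did not pass, HOX and MEIS genes had 7 of 10 members lower and 1 higher (adjusted p = 0.0631), with HOXA7 at -1.81, HOXB9 at -1.32, HOXA5 at -1.28 and HOXA9, which rose, at 0.55. Neutrophil and phagocyte maturation genes had 7 of 12 higher and 3 lower (adjusted p = 0.0675): NCF1 (3.26), a subunit of the NADPH oxidase, and the gelatinase gene MMP9 (1.83) rose and the receptor gene TREM1 (-2.29) fell. Without OCI-AML3 parental replicate 1 both of these lists passed (adjusted p = 0.0495 each), and without parental replicate 3 the HOX and MEIS list did (adjusted p = 0.0494). The HOX and MEIS list also passed with a pseudocount of 0.1 (adjusted p = 0.0448) and after rescaling by medians of ratios (adjusted p = 0.0440). Their ranges over the alternatives were 0.0440 to 0.0946 and 0.0495 to 0.114. Monocyte and macrophage genes had 11 of 20 higher and 9 lower (adjusted p = 0.288), with the scavenger receptor gene CD36 (4.19) and the co-stimulatory gene CD86 (3.23) higher and the lysosomal marker CD68 (-2.02) lower. Interferon-stimulated genes had 3 of 17 higher and 8 lower (adjusted p = 0.122). Primary granule genes had 2 of 10 higher and 5 lower (adjusted p = 0.416). CTSG (-2.48) and PRTN3 (-1.99), proteases of the azurophil granule, fell. Of 12 p53 targets 8 were higher and 4 lower (adjusted p = 0.1496). Among them GDF15, a stress cytokine (2.61), and the cyclin-dependent kinase inhibitor gene CDKN1A (2.05) rose and EDA2R (-1.83) fell. Adhesion and homing receptors had 4 of 6 higher and 2 lower (adjusted p = 0.140), with CXCR4 at 1.56 and SELPLG at -2.42. Inhibitors of cyclin-dependent kinases with D cyclins had 3 of 5 higher and 2 lower (adjusted p = 0.416). MHC class II genes had 1 of 5 higher and 2 lower (adjusted p = 0.762). Stem cell genes had 2 of 7 higher and 4 lower (adjusted p = 0.762; median -0.72, mean 0.31), and immediate early and heat shock genes had 3 of 8 higher and 4 lower (adjusted p = 0.873).

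In OCI-AML2, CEACAM6, S100A8, S100A9, BPI and CCL2 were among the genes with the largest rises in both knockout clones, and OSCAR and IL32 among those with the largest falls. CEACAM6, a granulocyte adhesion molecule, rose from 1.14 ± 0.234 TPM to 117 ± 13.2 in clone 1 and 169 ± 8.87 in clone 2 (103-fold and 148-fold, log2 SE 0.10, adjusted p = 5.4e-18 and 1.6e-18). S100A8 and S100A9, the subunits of calprotectin, rose from 15.3 ± 2.62 to 857 ± 166 and 634 ± 85.7 TPM and from 79.3 ± 7.34 to 2539 ± 222 and 1552 ± 138 TPM. BPI, a bactericidal granule protein, rose 90.9-fold to 171 ± 21.9 TPM in clone 1 and 17.99-fold to 33.8 ± 5.42 TPM in clone 2. CCL2, a monocyte chemoattractant, rose from 0.553 ± 0.110 to 18.04 ± 2.94 and 146 ± 7.90 TPM. OSCAR, an immune receptor of osteoclasts and myeloid cells, fell from 53.02 ± 3.93 to 9.49 ± 1.26 and 3.64 ± 0.645 TPM. The cytokine gene IL32 fell from 37.1 ± 2.01 to 6.13 ± 1.35 and 2.49 ± 0.626 TPM.

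The remaining large rises in OCI-AML2 were IL2RG, the common cytokine receptor chain (9.53 ± 0.191 to 130 ± 24.8 and 90.7 ± 10.4 TPM), and HLA-DRB1, an MHC class II chain (1.80 ± 0.622 to 56.4 ± 3.49 and 22.2 ± 2.35 TPM). They also held AKR1C3 (1.84 ± 0.337 to 29.4 ± 2.46 and 31.8 ± 5.08 TPM) and RAB34, a small GTPase gene (1.54 ± 0.240 to 37.1 ± 1.81 and 42.4 ± 0.595 TPM). MAP1LC3A, an autophagy gene, SLC26A9, an anion transporter gene, and TPBG completed the 12. Across the 12 the mean log2 rise was 3.37 to 6.05, and the highest adjusted p was 6.2e-10. MGAM2, a relative of the brush border enzyme maltase-glucoamylase, fell from 22.5 ± 0.990 to 0.333 ± 0.0666 and 0.637 ± 0.0416 TPM. GALNT11, a glycosyltransferase gene at 7.72 ± 1.26 TPM in parental cells, was listed at 0 in the 6 clone libraries. MGAM2, GALNT11 and CASP2 lie in a run of 31 neighbouring genes in the table whose median log2 change was -1.10 in clone 1 and -0.83 in clone 2. APBA1, C2orf74, COCH, QPCT, FAM129C, the homeobox gene DLX2, the GABA receptor gene GABRG1 and CASP2 itself were the other large falls. The 12 ran from -3.99 to -2.55 with a highest adjusted p of 5.3e-09. In all, 1695 sets changed in both clones, 1052 higher and 643 lower, of which 1020 had a symbol. The count is that of changes shared by clones that differed from each other in 2599 sets, and with a log2 change of at least 1 it was 377.

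Of the gene lists in OCI-AML2, 4 of 13 passed with the preset correlation and 1 with an estimated one. Beside the counts of members, 636 of all 2296 tested sets with a symbol were higher and 384 lower in both OCI-AML2 clones. Interferon-stimulated genes rose, with 14 of 17 members higher and 1 lower (median 0.69, adjusted p = 0.000944; adjusted p = 0.0318 with an estimated correlation). OAS2 (1.61), a sensor of double-stranded RNA, and IFI44 (1.54) rose, while ISG15 (-0.74), a ubiquitin-like modifier, was the lower member. OAS2 went from 1.96 ± 0.287 to 10.3 ± 0.686 and 6.20 ± 0.554 TPM. Some rises lay at low levels, since IFI27 and IFI44L were under 1 TPM in OCI-AML2 parental cells. Their OCI-AML3 levels carry them past a minimum of 5 TPM. Neutrophil and phagocyte maturation genes rose, with 9 of 12 higher and 2 lower (median 1.08, adjusted p = 0.0128; adjusted p = 0.130 with an estimated correlation), among them S100A8 (5.50), S100A9 (4.63) and MMP9 (1.84). HOX and MEIS genes rose, with 7 of 10 higher and 0 lower (median 1.05, adjusted p = 0.0256; adjusted p = 0.172 with an estimated correlation). HOXA7 went from 13.5 ± 1.202 to 52.1 ± 9.05 and 77.4 ± 8.31 TPM, and HOXA9, a driver of self-renewal in leukaemia, from 59.0 ± 5.12 to 133 ± 8.78 and 166 ± 5.73 TPM. Integrated stress and unfolded protein response genes fell, with 4 of 7 lower and 1 higher (median -0.52, adjusted p = 0.0490; adjusted p = 0.130 with an estimated correlation). CHAC1 (-2.03), DDIT4, an mTOR inhibitor (-1.93), and SLC7A5 (-1.56) fell, and SLC7A11 (0.96) rose. CHAC1 and DDIT4 fell further in clone 2 (0.0966 and 0.122 of parental TPM) than in clone 1 (0.557 and 0.541). Compared directly, 3 of the 7 members were lower in clone 2 than in clone 1 and 2 higher. The integrated stress call held in 11 of 25 settings (range of adjusted p 0.0388 to 0.0743). It ended with a pseudocount of 0.1 (0.0604), a minimum of 5 TPM (0.0743), rescaling by medians of ratios (0.0600) and the replicate block (0.0585). It also ended without OCI-AML2 parental replicate 2 (0.0539), clone 1 replicate 1 (0.0535), clone 2 replicate 1 (0.0541) or clone 2 replicate 3 (0.0520), and without any of 6 OCI-AML3 libraries (0.0503 to 0.0538). The HOX call ended with a pseudocount of 0.1 (adjusted p = 0.0682, range 0.0153 to 0.0682) and the neutrophil call with a minimum of 5 TPM (adjusted p = 0.0743, range 0.00460 to 0.0743).

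In the OCI-AML2 lists that did not pass, primary granule genes had 4 of 10 higher and 0 lower (adjusted p = 0.0980), with CEACAM6, BPI and the serine protease gene PRSS57 (1.205) higher and PRTN3 at 0.05. MHC class II genes had 3 of 5 higher and 0 lower (adjusted p = 0.109). Targets of p53 had 6 of 12 higher and 2 lower (adjusted p = 0.162), with PHLDA3 (2.71) and EDA2R (1.32) higher and GDF15 (-0.92) lower. Immediate early and heat shock genes had 0 of 8 higher and 3 lower (adjusted p = 0.0917), including the AP-1 genes JUN (-0.94) and FOS (-0.73). Adhesion receptors had 1 of 6 higher and 1 lower, inhibitors of cyclin-dependent kinases with D cyclins 2 of 5 higher and 0 lower, and stem cell genes 4 of 7 higher and 1 lower, with the polycomb gene BMI1 at 1.59 higher. Monocyte and macrophage genes had 4 of 20 higher and 5 lower (median 0.08, mean -0.07). For these 4 lists the adjusted p was 0.277. Genes of signals that regulate pluripotency had 4 of 17 higher and 4 lower (adjusted p = 0.971). Adjusted over the list alone, each count was the same.

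**Figure D2:**
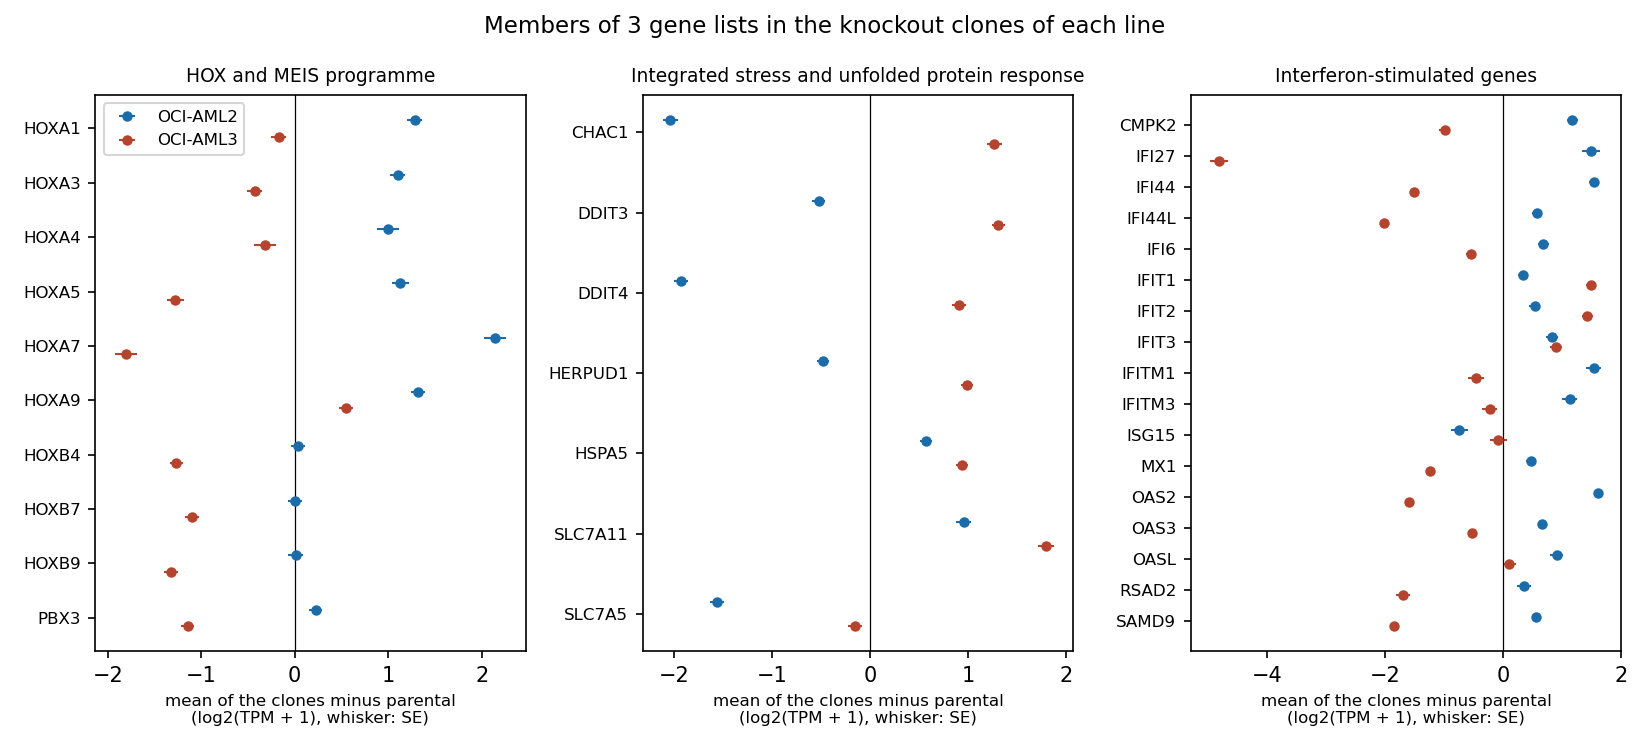
Log2 change of each member of 3 gene lists (HOX and MEIS, integrated stress and unfolded protein response, interferon-stimulated), as the mean of both clones minus parental on the log2(TPM + 1) scale with SE (horizontal axis), for OCI-AML2 (blue) and OCI-AML3 (red), 3 libraries per group. HOXA7 lies at 2.14 in OCI-AML2 and -1.81 in OCI-AML3, and CHAC1 at -2.03 and 1.27.

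The change from parental to clone differed between the lines in 2707 sets, 1069 with the more positive change in OCI-AML3 and 1638 in OCI-AML2, and 1767 of these had a symbol. CHI3L1 led with a difference of 9.61 (SE 0.18, adjusted p = 1.3e-17). Against its rise in OCI-AML3, CHI3L1 went from 9.76 ± 0.370 to 7.95 ± 0.813 and 5.15 ± 1.75 TPM in OCI-AML2. CD14 (5.49) and ALOX5AP (5.15), which presents arachidonic acid to 5-lipoxygenase, rose in OCI-AML3 and fell in OCI-AML2. ALOX5AP went from 27.3 ± 3.36 to 410 ± 29.8 and 553 ± 51.9 TPM in OCI-AML3 and from 787 ± 47.7 to 220 ± 33.6 and 646 ± 60.5 TPM in OCI-AML2. In the other direction, IFI27 (-6.30), CRIP1 (-4.86), a LIM domain protein, and RASL11A (-4.80) fell in OCI-AML3 and rose in OCI-AML2. CRIP1 went from 365 ± 3.69 to 31.02 ± 7.08 and 28.7 ± 2.64 TPM in the first and from 124 ± 36.0 to 299 ± 18.3 and 294 ± 55.5 TPM in the second. CEACAM6 (-5.97) and S100A8 (-4.87) rose in OCI-AML2 and stayed at or below 2.31 TPM in the OCI-AML3 group means.

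Of the lists, 4 of 13 differed between the lines with the preset correlation and 1 with an estimated one. Beside the counts of members, 704 of all 2296 tested sets with a symbol had the more positive change in OCI-AML3 and 1063 the more negative. Integrated stress and unfolded protein response genes had the more positive change in OCI-AML3 for 6 of 7 members and the more negative for 0 (median difference 1.46, adjusted p = 0.00141; adjusted p = 0.0234 with an estimated correlation), led by CHAC1 (3.30) and DDIT4 (2.83). HOX and MEIS genes had the more negative change in OCI-AML3 for 10 of 10 (median -1.35, adjusted p = 0.00392; adjusted p = 0.0904 with an estimated correlation), led by HOXA7 (-3.95) and HOXA5 (-2.41). For HOXB4, HOXB7 and HOXB9, listed at 0 in OCI-AML2 parental cells and clone 1, the difference is that of OCI-AML3 alone. Interferon-stimulated genes did so for 11 of 17, with 2 the other way (median -1.71, adjusted p = 0.0194; adjusted p = 0.0904 with an estimated correlation). Primary granule genes did for 7 of 10, with 1 the other way (median -1.93, adjusted p = 0.0194; adjusted p = 0.267 with an estimated correlation). Monocyte genes had 10 of 20 more positive and 5 more negative (adjusted p = 0.0858) and signals regulating pluripotency 3 and 12 of 17 (adjusted p = 0.109; 0.0393 without a filter on low values, range 0.0393 to 0.146). Each count was the same adjusted over the list alone. For scale, rescaling by medians of ratios shifted the median of all genes by 0.11 and 0.13 in the OCI-AML3 clones and by 0.18 in the difference between lines. With it the higher and lower counts became 1442 and 1495 in OCI-AML3 (1267 and 1692 as reported), 928 and 748 in OCI-AML2 (1052 and 643), and 1244 and 1451 for the difference (1069 and 1638).

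Changes in the same direction in both clones of both lines were found in 511 sets, 284 higher and 227 lower, of which 350 had a symbol. AKR1C3 led the rises, and BCL2A1, an anti-apoptotic BCL2 relative, went from 1.47 ± 0.297 to 40.6 ± 5.42 and 38.7 ± 4.76 TPM in OCI-AML3 and from 4.88 ± 1.03 to 21.8 ± 2.42 and 23.8 ± 3.36 TPM in OCI-AML2. ECHDC2, a mitochondrial enzyme gene, rose from 0.450 ± 0.0954 to 10.2 ± 0.616 and 10.2 ± 0.554 TPM in OCI-AML3 and from 0.233 ± 0.119 to 11.9 ± 1.43 and 10.1 ± 0.369 TPM in OCI-AML2. PYGM, CCL2, CYBB, S100A9 and the metallothionein gene MT2A completed the 8 largest rises by the mean over the lines, with log2 rises in single clones from 0.40 to 7.42. The rank of PYGM comes from OCI-AML3, since in OCI-AML2 it went from 0.360 to 0.793 and 0.810 TPM. MT2A went from 59.8 ± 3.57 to 928 ± 58.1 and 1148 ± 11.9 TPM in OCI-AML3 and from 116 ± 18.4 to 184 ± 0.221 and 230 ± 64.0 TPM in OCI-AML2. PLTP fell in both lines, in OCI-AML2 from 215 ± 17.2 to 113 ± 10.5 and 64.2 ± 6.29 TPM. TIFAB, an inhibitor of innate immune signalling, fell from 13.0 ± 0.956 to 1.64 ± 0.159 and 1.86 ± 0.665 TPM in OCI-AML3 and from 28.8 ± 1.24 to 6.89 ± 0.715 and 9.47 ± 0.787 TPM in OCI-AML2. COCH, ST6GAL1, FSD1, TMEM121B, the phosphatase gene DUSP8 and PROCR, the endothelial protein C receptor, were the other falls. PROCR lost its call without OCI-AML2 clone 1 replicate 2 (adjusted p = 0.0543), parental replicate 1 (adjusted p = 0.0505) or parental replicate 2 (adjusted p = 0.0536). Lists that changed independently in the lines would share 302 higher and 247 lower sets, so the overlap of 284 and 227 was below that number. Selection of the table on changes in the clones can itself lower the overlap. Among 1083 sets listed for the parental difference alone it was 22 and 20, where independent lists give 21.1 and 19.5. This listing was inferred from the values. These sets fell short of a log2 ratio of 0.6 shared by both OCI-AML3 clones and of 0.6 in OCI-AML2 clone 1. They are therefore no check free of selection. Of all 4413 sets, 191 and 368 changed in opposite directions. Across the 4413 sets the log2 changes of the lines, averaged over clones, had a Pearson r of 0.02 and a Spearman rho of 0.01, where genes are not independent replicates.

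Between the parental lines 3997 of 4413 sets differed, 2082 higher in OCI-AML3 and 1915 higher in OCI-AML2. Interferon-stimulated genes were higher in OCI-AML3 in 17 of 17 members (median 4.94, adjusted p = 5.7e-06; adjusted p = 0.00505 with an estimated correlation), and this was the single list of 13 that passed. That list names 36 genes, of which 35 stand in the table and 17 had a settled symbol. Among all 2296 tested sets with a symbol, 1000 were higher in OCI-AML3 and 957 higher in OCI-AML2. IFI27 stood at 1525 ± 99.6 against 0.217 ± 0.225 TPM, and IFITM3, which blocks viral entry, at 1746 ± 126 against 10.95 ± 1.93 TPM. OAS2 stood at 230 ± 6.83 against 1.96 ± 0.287 TPM and IFI44L at 239 ± 6.77 against 0.433 ± 0.127 TPM. MAP1LC3A, BEX1, the kinase gene MATK, MT1A, GAMT and CBS, enzymes of creatine and cysteine synthesis, were also among the 10 genes highest in OCI-AML3, with a highest adjusted p of 2.0e-12. In OCI-AML2, ORM1, an acute-phase glycoprotein, stood at 4023 ± 298 against 0.1 ± 0.173 TPM (log2 difference -11.85, SE 0.20, adjusted p = 2.2e-19). The apolipoprotein gene APOC2 stood at 537 ± 79.5 against 0.413 ± 0.211 TPM and DEFB1, a defensin, at 252 ± 35.2 against 0.103 ± 0.179 TPM. PDLIM1, the homeobox genes RHOXF2 and RHOXF2B, SNURF, VAT1L and HAPLN4 were also among the genes highest in OCI-AML2. RHOXF2 and RHOXF2B were listed at 0 in the OCI-AML3 parental libraries. Of 12 p53 targets 9 were higher in OCI-AML3 and 2 in OCI-AML2 (adjusted p = 0.124), of 10 HOX and MEIS genes 4 and 6 (adjusted p = 0.795), and the other lists had adjusted p-values from 0.159 to 0.987. Each count was the same adjusted over the list alone. The table was selected in part for this contrast, so the share of sets that differed is not that of the transcriptome.

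Fewer sets differed between the clones of OCI-AML3 than between those of OCI-AML2. Clone 2 differed from clone 1 in 301 sets in OCI-AML3, 174 higher and 127 lower, and in 2599 sets in OCI-AML2, 1318 higher and 1281 lower. The median absolute log2 difference between clone means was 0.113 in OCI-AML3 and 0.342 in OCI-AML2, with a replicate SD of 0.125. In OCI-AML3 the smaller count varied with the libraries used and with the fit. It was 136 and 159 without clone 1 replicates 1 and 2, 171 and 102 without clone 2 replicates 1 and 2, 168 with the replicate number as a block, 433 with a pseudocount of 5 and 393 after rescaling by medians of ratios. Among the 301 sets were 16 of 17 interferon-stimulated genes, each lower in OCI-AML3 clone 2 (median -0.89), a count made after the values had been seen. IFI27 was at 95.3 ± 6.93 TPM in clone 1 and 29.8 ± 2.97 TPM in clone 2, and IFI44 at 50.5 and 25.5 TPM. In OCI-AML2, 5 of the 17 were higher in clone 2 and 6 lower. In the same line, CCL2 was at 18.04 ± 2.94 TPM in clone 1 and 146 ± 7.90 TPM in clone 2, and BPI at 171 ± 21.9 and 33.8 ± 5.42 TPM. The changes of both clones against the shared parental libraries had a Pearson r of 0.983 across sets in OCI-AML3 (Spearman rho 0.973, covariance 1.23) and 0.708 in OCI-AML2 (Spearman rho 0.603, covariance 0.481). Simulated unchanged clones gave r of 0.497 and 0.502 with covariances of 0.00691 and 0.00695. Among 1083 sets listed for the parental difference alone r was 0.806 in OCI-AML3 and 0.361 in OCI-AML2, where the simulation gave 0.493 and 0.492. The covariances were 0.0854 and 0.0602, against 0.00604 and 0.00599 simulated, and 60.7% of these sets had the same sign in both OCI-AML2 clones, where it gave 66.5%. Higher sets shared by both clones numbered 1267 in OCI-AML3 and 1052 in OCI-AML2, where independent lists give 436 and 592. Lower sets numbered 1692 and 643, where they give 751 and 254. In OCI-AML2, 175 sets were higher in clone 1 and lower in clone 2, and 105 the reverse. With 3 parental libraries the controls cannot be split into parts of at least 2, so part of the excess may come from sharing them. The table was selected for changes in both OCI-AML3 clones but in clone 1 alone of OCI-AML2, which can itself raise r in OCI-AML3. The simulation left this selection out. The 1083 sets fell short of these criteria, with no bound on OCI-AML2 clone 2. There the SD of the changes in clones 1 and 2 was 0.321 and 0.331 in OCI-AML3 and 0.256 and 0.652 in OCI-AML2.

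**Figure D3:**
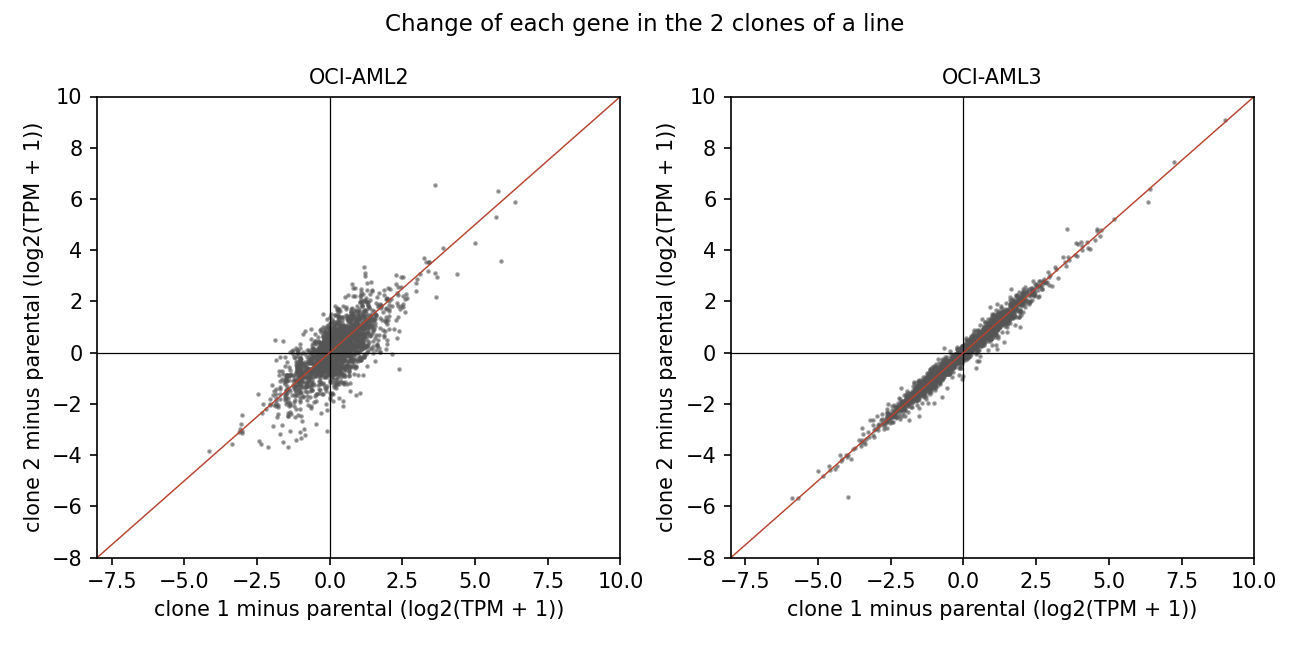
Log2 change of clone 2 (vertical axis) against that of clone 1 (horizontal axis), both over parental cells, with a panel per cell line. Each of the 2296 tested sets with a settled symbol is 1 point. Over all 4413 tested sets r was 0.983 in OCI-AML3 and 0.708 in OCI-AML2. The table was selected on both OCI-AML3 clones but on clone 1 alone in OCI-AML2, which shapes this contrast.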

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

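The counts over other splits of the libraries and each test of an explanation below were chosen after the result was seen, while the tests of a difference between the cell lines were planned.

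The response differed between the cell lines, by a test of the difference itself, in 2707 of 4413 sets of values. Among 1083 sets listed for the parental difference alone, which did not meet the fold criterion in both OCI-AML3 clones or in OCI-AML2 clone 1, it differed in 259 (23.9%). More positive in OCI-AML3 than in OCI-AML2 were the changes of CHI3L1 (difference of log2 changes 9.61), PYGM (6.93), IGFBP3 (6.11), COL8A2 (5.83), CD14 (5.49), NTSR1 (5.35), ALOX5AP (5.15), RTL8B (4.95) and CASP2 itself (2.95). More negative were those of IFI27 (-6.30), CEACAM6 (-5.97), MT1A (-5.94), S100A16 (-5.50), S100A8 (-4.87), CRIP1 (-4.86), RASL11A (-4.80) and MAP1LC3A (-4.74). The SE of these differences was at most 0.41 and the highest adjusted p among the 16 largest was 1.1e-09. The lists that differed with the preset inter-gene correlation were integrated stress and unfolded protein response genes (median 1.46), HOX and MEIS genes (-1.35), interferon-stimulated genes (-1.71) and primary granule genes (-1.93). With an estimated correlation the set test gave adjusted p-values of 0.0234, 0.0904, 0.0904 and 0.267, so only the first passed. Part of such a difference may depend on where each line started, which was not tested. IGFBP3 and MT1A were listed at 0 in OCI-AML2 parental cells and clone 1, so their differences are almost those of OCI-AML3 alone. IFI27, at 0.217 TPM in parental OCI-AML2 cells, had little room to fall, though it rose 6.85-fold and 17.4-fold in the clones. Single libraries were not tested for standing apart from their groups of 3.

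Chance assignment of libraries to groups was examined by refitting other splits of the same libraries. For the difference between lines 1 of 100 splits, the real one, gave as many sets (2707 against at most 1567). For changes in both lines it was 1 of 100 (511 against at most 206) and for OCI-AML2 1 of 100 (1695 against at most 1537). For OCI-AML3 4 of 100 splits gave as many (2959 against at most 3001). These 4, the real split and 3 that mixed only the clones, kept the parental libraries together. With parental libraries mixed the highest count was 154. The table was selected for changes between the real groups, which by itself favours the real split. Splits of libraries also leave open chance differences between single clones and their parental cells. The counts over splits therefore cannot exclude chance. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In each of these the real split alone, 1 of 10, reached its count: 3997 against at most 0 other for the parental lines, and 3188 and 3227 against at most 0 for the OCI-AML3 clones. It was 2471 against at most 1 and 2900 against at most 0 for OCI-AML2 clones 1 and 2. Between clones it was 301 against at most 5 in OCI-AML3 and 2599 against at most 1 in OCI-AML2.

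CASP2 mRNA fell in the OCI-AML2 clones and did not pass in the OCI-AML3 clones labelled as knockouts. An exchange of clone and parental libraries in OCI-AML3 stays open: the lowest parental library had 28 TPM, but an edited transcript need not be low. In OCI-AML2 clone 1 the neighbours of CASP2 fell by a median log2 of -1.10 and CASP2 further (-3.05), which argues against a fall of the neighbourhood as the whole cause, although 2 of the 30 other genes fell more on the log2(TPM + 1) scale and 3 by ratio of TPM. Different edits in the lines, with transcript decay or a deletion in OCI-AML2 and a stable edited transcript in OCI-AML3, may explain the difference, and so may intact CASP2 in OCI-AML3, and none of these was tested.

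Runs of neighbouring genes fell together in OCI-AML2 clone 1, a pattern found by looking: the genes from AHRR to IQGAP2 (53 genes, median log2 change -1.29) and from TRIM24 to ESYT2 (31 genes, -1.10) stood out of 1095 genes in order, with a largest running median of 1.59 in absolute value against 1.05 for 95% of 1000 shuffled orders. Shuffled orders hold the same selected genes, and 0 of 1000 reached 1.59, which argues against selection on clone 1 as the whole source, though not as one that enlarged the size. In clone 1 neighbours correlated at 0.280 with settled symbols, where the highest of 1000 shuffled orders gave 0.0893. Printed symbols that settled ones contradict gave -0.0235 there. Wrong symbols stay open, since such printed symbols still gave 0.114 in clone 2. The median of these genes in clone 2 was -0.84, and a difference in the parental libraries that the clones share cannot be told apart from one in the clones, since the table was chosen on clone 1 and the clones differed by 0.37 in these runs. Loss of a copy of these segments in cells that gave rise to both clones may explain median ratios of 0.372 and 0.430 in clone 1 and 0.543 and 0.513 in clone 2, a hypothesis that was not tested on DNA.

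The OCI-AML3 clones were close to each other, with a median absolute log2 difference of 0.113, which argues against the shared parental libraries as the source, since these do not enter it. Selection of the table on both OCI-AML3 clones stays open. Of sets listed for the parental difference alone 6.74% differed between the OCI-AML3 clones and 62.5% between the OCI-AML2 clones, but the selection, which held OCI-AML2 clone 1 and not clone 2, shapes that contrast. The same library deposited for both clones is argued against by a highest correlation of 0.994 between libraries of the clones, below the lowest within either clone, also over the 3356 sets of known replicate order (0.9951 against 0.9953, an alternative chosen after seeing the data). A common effect of the knockout and a common origin of the clones after editing may each explain it, and nothing in the design separates them.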

How the results depend on the processing

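The comparisons gave 350 values that stayed within their bounds over the alternatives, 30 that moved and 1 that became stronger. A count was within bounds up to 1.5 times above or below the reported one, a correlation within the range from leaving out single libraries, and CASP2 with the same direction and side of the threshold. Correlations from leaving out single libraries set that range, so they were within bounds by construction. For named genes, 8926 of 9047 values kept direction and side of the threshold, 68 fell short of it, 50 newly passed and 3 reversed. Where no cause is named below, the cause was not tested.

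With a log2 change of at least 1 required, fewer sets pass by construction: 1240 in both OCI-AML3 clones, 377 in both OCI-AML2 clones, 1297 for the difference between lines, 37 in both lines, 2658 between parental lines, 1398 and 1374 in OCI-AML3 clones 1 and 2, 640 and 882 in OCI-AML2 clones 1 and 2, and 7 and 510 between the clones of OCI-AML3 and OCI-AML2. The mean of the clones in place of both gave 2760 for OCI-AML2, and 970 for a change in the same direction in each line.

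The 301 sets between the OCI-AML3 clones became 166 with a pseudocount of 0.1, 168 with replicate number as a block and 155 with only the compared groups, and within bounds 433 with a pseudocount of 5 and 393 after rescaling by medians of ratios. Leaving out 1 library gave 102 (without clone 2 replicate 2) to 341 (without clone 2 replicate 3), and 136 and 159 without clone 1 replicates 1 and 2, and 171 without clone 2 replicate 1. The replicate numbers do not pair the libraries: 4 of 18 pairs correlated best with their own number (-0.362 to 0.189).

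Called lists numbered 2 in OCI-AML2 with a pseudocount of 0.1 and 2 with a minimum of 5 TPM (4 as reported), and 1 in OCI-AML3 with that minimum (2 as reported). An estimated inter-gene correlation left 0 in OCI-AML3, 1 in OCI-AML2 and 1 for the difference between lines. Leaving out 1 library gave 2 to 4 lists in OCI-AML3 (4 without parental replicate 1) and 3 to 4 in OCI-AML2.

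The agreement of the OCI-AML2 clones was 0.752 with a pseudocount of 0.1 and 0.672 with 5, and that of the lines 0.011 after rescaling by medians of ratios. CASP2 in OCI-AML3 clone 2 passed with that rescaling (0.30, adjusted p = 0.0148). For the difference between lines, FGF2 (-1.15) and SPARC (1.09) reversed with a pseudocount of 0.1 and MMP9 (0.69) with 5.

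Leaving out 1 library gave 2850 to 2927 sets in both OCI-AML3 clones, 1568 to 1674 in both OCI-AML2 clones, 2650 to 2707 for the difference and 468 to 514 in both lines. Depth is unknown, so what it limits cannot be given; levels under 1 TPM carry the least weight.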

Other observations

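The scan of neighbouring genes, its alternatives and the tests of correlation between neighbours were chosen after the data were seen; the lists were not.

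Short lists without a set test added detail. Cholesterol synthesis genes fell in OCI-AML3 in 4 of 4 members (median -1.07), DHCR7, the last enzyme of the pathway, going from 103 to 46.4 and 51.6 TPM; in OCI-AML2 1 of 4 rose and 1 fell, and 2 rose adjusted over the list alone. The fall was that of INSIG1, from 172 to 137 and 104 TPM, which lies in the run from TRIM24 to ESYT2. Glycolysis and hypoxia genes had 3 of 4 lower and 1 higher in OCI-AML3 (median -1.51) and 2 lower and 1 higher in OCI-AML2. Erythroid and megakaryocyte genes had 3 of 4 higher and 1 lower in OCI-AML3 and 2 of 4 higher and 0 lower in OCI-AML2, among them NFE2, a transcription factor of platelet formation, which rose from 0.940 to 11.8 and 12.1 TPM and from 8 to 27.2 and 30.2 TPM. Pluripotency factors had 2 of 4 higher in OCI-AML3 and 3 of 4 in OCI-AML2, where LIN28B, an inhibitor of let-7 processing, rose from 5.56 to 13.7 and 25.7 TPM. RICTOR, a subunit of mTORC2, rose in OCI-AML3 and fell in OCI-AML2, where it lies in the run from AHRR to IQGAP2 whose median log2 change was -1.29 in clone 1 and -0.85 in clone 2, and in no run in 6 of 18 settings of the scan.

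Libraries of a group correlated at 0.993 to 0.997, and those of different OCI-AML3 clones at 0.990 to 0.994, against 0.954 to 0.957 for the OCI-AML2 clones. The first principal component held 79.1% of the variance and the second 11.1%.

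Neighbouring genes also changed together, more weakly, in OCI-AML2 clone 2 (r 0.181) and in the OCI-AML3 clones (0.0948 and 0.0933), with permutation p = 0.001, 0.002 and 0.001, where 0.001 is the smallest 1000 shuffles can give. Under printed symbols that settled ones contradicted, the correlation was -0.0235 in OCI-AML2 clone 1 (permutation p = 0.68) and 0.114 in clone 2 (permutation p = 0.006). Of 18 settings of the scan, 18 had a run ending at IQGAP2 or ZBED3 and 12 one ending at ESYT2, which was absent with windows of 11 genes. With these windows the first run split, into one ending at MYO10 and one starting at PTGER4 or EMB. A further run of lower genes, ending at CENPBD1, appeared in 6 settings and a run of higher genes, ending at NCF1, in 1. In the runs, 65 of 84 genes were lower by more than 0.4 in clone 2 (77.4%, against 30.6% of 1011 genes outside). The runs were defined by falls in clone 1, which shares its parental libraries with clone 2. Over all tested sets the changes of these clones correlated at 0.708, so a higher share in the runs was favoured in advance. The genes outside were not matched for a fall in clone 1. In the OCI-AML3 clones the median changes of the genes in the runs were 0.04 and 0.07.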
